A study of Mus musculus with 6 samples.

How the data were processed

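The series holds 6 ChIP-seq libraries from mouse cerebellar granule cell nuclei, 1 each for H3K4me3, H3K9me3, H3K27ac and H3K4me1 and 2 inputs. Per the labels' protocols, each sort used a pool of 4 cerebella, from 2 animals of each sex, tissue homogenates were fixed with formaldehyde, and chromatin of sorted nuclei was sonicated and immunoprecipitated with a kit for low cell numbers. H3K4me3, H3K9me3 and the input that goes with them came from nuclei of a NeuroD1-EGFP-Rpl10a line sorted by fluorescence. H3K27ac, H3K4me1 and their input came from C57BL/6J nuclei gated by size, which per the labels' protocols raised the granule cell share from 65 to 70% to 92 to 96%. A contrast of marks between these pairs is therefore also a contrast of strain and sort. With 1 library per mark, samples were grouped by mark, nothing could be averaged, and no test across samples was possible.

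Per the submitters' processing notes, the tools were Bowtie2 2.1.0, SAMtools and HOMER 4.8 with the mm10 assembly; their roles and settings are not given in the sources used here. The authors deposited 4 lists of genomic regions named promoters, non-regulatory, primed enhancers and active enhancers, which per the labels draw on H3K4me3, H3K27ac, H3K4me1 and both inputs. The regions run in steps of 200 bp without a score, and the segmentation tool and its thresholds are not given in the sources used here. A segmentation into fixed bins sets the smallest region and joins neighbouring bins of 1 state, so region counts depend on it. The authors also deposited a linear ratio of H3K9me3 over H3K27ac for each RefSeq transcript, per the file headers; it drew on both marks and both inputs per the labels. Whether the marks were scaled to depth or input is not stated, and no counts were given, so the depth per library, and the precision it would set, is unknown and no interval was computed. The comparison plan had assumed the inverse direction, active over repressive mark, and the neutral value was taken as 1 for the linear ratio.

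The region lists count positions from 0 and were converted to positions from 1 for printing. TSSs and gene spans came from the 31161 transcripts of the per-gene table (2 blank lines were dropped), and 98.7% of their identifiers matched the RefSeq gene table of assembly GRCm38.p6, the primary assembly that mm10 names. Per-gene analyses used autosomal genes, each represented by its longest transcript (22171 genes), and left out 18 transcripts on unplaced contigs. A further 637 NR transcripts, the last in accession order, were left out of the per-gene analyses after the data had been seen: 190 of them form a stretch in which most values checked matched those of the next row, and 447 could not be placed before or after that point. They were kept in the distribution over transcripts. Values were taken to match within 2%, and spans to be the same when they shared 98% of the longer.

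A gene had a promoter state when a promoter region overlapped 1000 bp on either side of any of its TSSs, and an enhancer state when an enhancer overlapped its span. Regions were assigned first to TSSs, then to gene bodies, then to the space between genes, and set against 100 random placements of the same lengths on the same chromosomes (20 for distances). Each of the 20 gene lists, fixed before the data were examined together with the comparisons and most alternatives, was described by the percentile of its median ratio, or of its share of genes with a state, among 10000 random lists of the same size drawn from the same gene length deciles. Percentiles under 2.5 or over 97.5 are said to set a list apart; they describe these libraries and are not p-values. Named genes were the 10 highest and 10 lowest by ratio among genes of at least 5000 bp outside the pattern lists whose symbol is neither Gm followed by digits nor ends in Rik; other provisional symbols were kept, the 2 highest and 2 lowest members of each list of symbols, members whose state went against the rest, and the Tet genes. Named regions were the 2 longest of each state and those overlapping Neurod1, Gabra6, Zic1, Zic4 and Mecp2. Since 22 eligible genes were listed at 0, the 10 lowest above 0 were named instead, a choice made after the data were seen, and the further members named in each list were also chosen after their values were seen.

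Alternatives changed the TSS window, the overlap, the region and gene length minimum, the matching of random lists, the summary statistic and the enhancer distance, and, added after the data were seen, the handling of the left-out rows and of values listed at 0. List percentiles were tested on simulated ratios for the 22171 genes, with 100 lists of 20 genes lowered and 200 lists left unchanged. The number of lists was raised after first runs with fewer lists had given unstable shares. Of the 100 lowered lists, 100 were set apart on the low side at 0.25 times, 79 at 0.5 times and 31 at 0.7 times, so a list that is not set apart may still hold a modest difference. Among the 200 unchanged lists, 11, 10 and 8 were set apart in the same runs. The search for misplaced rows called 0 rows in a table of 30524 rows without a moved tail. That table was made by removing the rows already called, so the 0 was fixed in advance and says nothing of false calls. When a tail of 1500 rows was moved by 1 row, the search called 1592, so its limit errs towards leaving out more rows. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

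Several genes of the lists were not analysed here because the per-gene ratio covers autosomes, among them Mecp2, Syn1, Syp, Plp1, Dcx, Hprt, Pgk1 and Gata1 on the X chromosome, and because 5 others, Cx3cr1, Tmem119, C1qc, Tyrobp and Npas4, had no value used here.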

Results

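Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measured 4 histone H3 modifications in nuclei of cerebellar granule cells, the small excitatory neurons that make up most cells of the mouse cerebellum. H3K4me3 marks active promoters, H3K4me1 marks enhancers whether or not they are in use, H3K27ac marks active promoters and enhancers, and H3K9me3 marks heterochromatin. The series set out to examine how cytosine methylation and hydroxymethylation relate to MeCP2 binding in these neurons, and the histone maps divide its genome by chromatin state. There were 6 libraries, 1 for each modification and 2 inputs, each from 4 pooled cerebella (2 males and 2 females). H3K4me3, H3K9me3 and their input came from nuclei sorted by the fluorescence of a NeuroD1-EGFP-Rpl10a transgene. H3K27ac, H3K4me1 and their input came from C57BL/6J nuclei gated by size, a gate that raised the granule cell share from 65 to 70% to 92 to 96%. No group had a replicate, so no value below has a replicate error and no p-value was computed. The sequencing depth behind the regions and ratios is unknown. All coordinates are on mm10.

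The authors' segmentation asked where promoters and enhancers of granule cells lie, and it assigned a small part of the genome to them. Promoter regions numbered 9485, with a median length of 800 bp. They covered 9.38 Mb, which is 0.381% of the autosomes. Active enhancers numbered 8122, with a median of 2000 bp, and covered 25.7 Mb or 1.05% of the autosomes. Primed enhancers, which carry H3K4me1 in the usual definition, were the most numerous regulatory class at 30244 regions, with a median of 2200 bp, and covered 102.5 Mb or 4.16%. The remaining 94.4% of the autosomes was non-regulatory. As shares of the whole covered genome, X and Y included, the values were 0.344% for promoters, 3.76% for primed enhancers, 0.944% for active enhancers and 94.9% for non-regulatory sequence. Promoters and enhancers were listed on autosomes only, so counting X and Y lowers their shares and raises the non-regulatory one. The 4 lists shared 0 bp with each other and left 0 bp of the autosomes unassigned between regions. Keeping only regions of at least 1000 bp left 4370 promoters.

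The longest promoter region spanned 9.8 kb in Tnrc18 (chromosome 5, 142813801 to 142823600), followed by 7.8 kb at Btg1, an antiproliferative gene (chromosome 10, 96616001 to 96623800). The longest active enhancer covered 48.8 kb of Prkcz, which encodes an atypical protein kinase C (chromosome 4, 155261401 to 155310200), and the next covered 46 kb in the ankyrin gene Ank1 (chromosome 8, 23009801 to 23055800). The longest primed enhancer covered 138.4 kb of Rbfox3, which encodes the neuronal nuclear antigen NeuN (chromosome 11, 118602001 to 118740400). The next, of 92.8 kb, overlapped no transcript of the per-gene table (chromosome 8, 123537201 to 123630000). The longest non-regulatory regions were 5094.6 kb around Cntnap5a (chromosome 1, 112417401 to 117512000) and 4243.6 kb that included Aspm, Cdc73 and Cfh (chromosome 1, 139456201 to 143699800).

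The states at 4 loci of granule cell genes, Neurod1, Gabra6, Zic1 and Zic4, were named before the data were examined. Neurod1, a transcription factor of granule cell differentiation, lay wholly inside a promoter region of 4.2 kb (chromosome 2, 79452601 to 79456800). Zic1, a zinc finger factor of granule cells, was overlapped by a promoter region of 6 kb (chromosome 9, 91359401 to 91365400) and a primed enhancer of 1.2 kb. The neighbouring Zic4 began within an active enhancer of 21 kb (chromosome 9, 91367001 to 91388000), with no promoter region within 1 kb of its start. A promoter region of 0.6 kb lay near its 3' end, which itself fell in a non-regulatory region. In Gabra6, the granule cell subunit of the GABA-A receptor, promoter regions of 2 kb and 1 kb lay next to active enhancers of 7, 0.8 and 1.6 kb and a primed enhancer of 2 kb, while its 3' end fell in a non-regulatory region (chromosome 11, 42184601 to 42308200). Mecp2 lies on the X chromosome, for which the promoter and enhancer states were not analysed here.

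**Figure D1:**
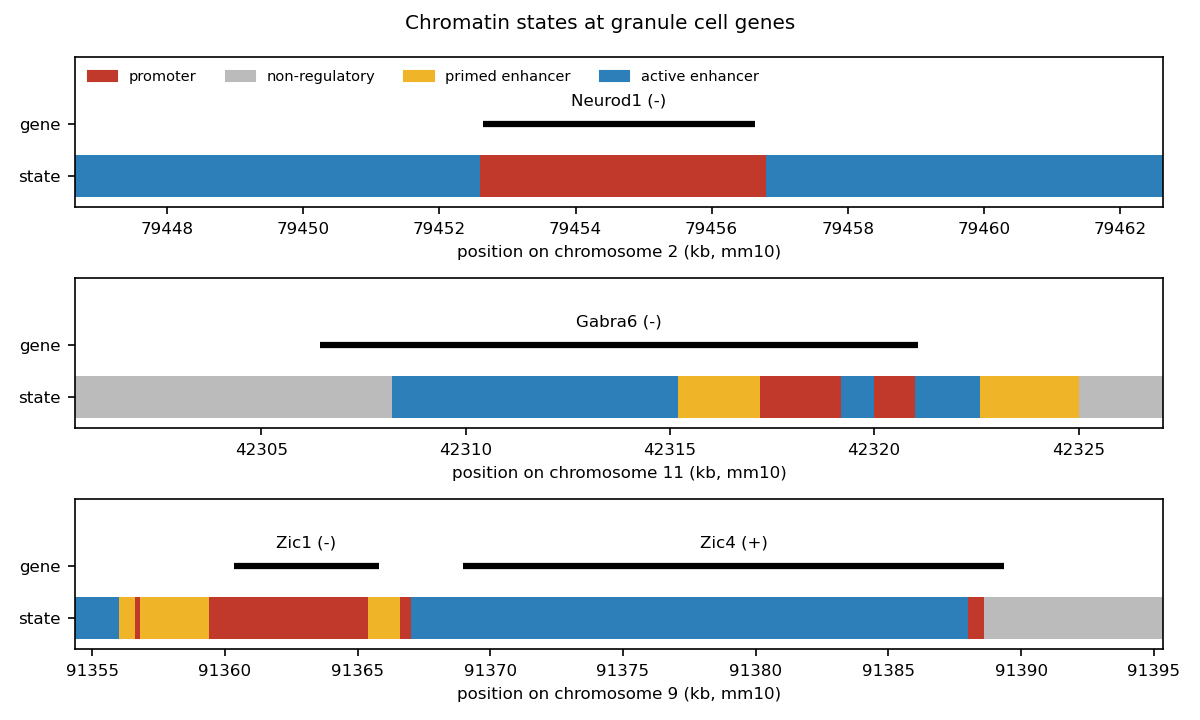
Chromatin states (coloured blocks) and genes (black lines, strand in brackets) at Neurod1, Gabra6 and the Zic1-Zic4 pair, each with flanking sequence, against the position in kb on mm10. Neurod1 lies inside the promoter region of 4.2 kb and most of Zic4 inside the active enhancer of 21 kb.

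The states differed in where they lay relative to genes. Of the promoter regions, 75.7% overlapped a window of 1 kb on either side of an annotated transcription start site (TSS), 25.9 times the 2.93% of regions of the same lengths placed at random. For primed enhancers the share was 32.8% against 5.00% at random, and for active enhancers 15.0% against 4.77%. Active enhancers lay mostly in the rest of gene bodies, at 56.8% against 37.7% at random, and primed enhancers did so at 45.5% against 37.7%. Between genes lay 11.4% of promoter regions, 21.7% of primed enhancers and 28.2% of active enhancers, where random placement gave 57.3 to 58.7%. Promoter regions without a TSS within 1 kb numbered 2301, with a median length of 400 bp, against 1000 bp for those with a TSS. Every share at the TSS depended on the window and overlap used, and stayed above random placement under each of those tried.

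**Figure D2:**
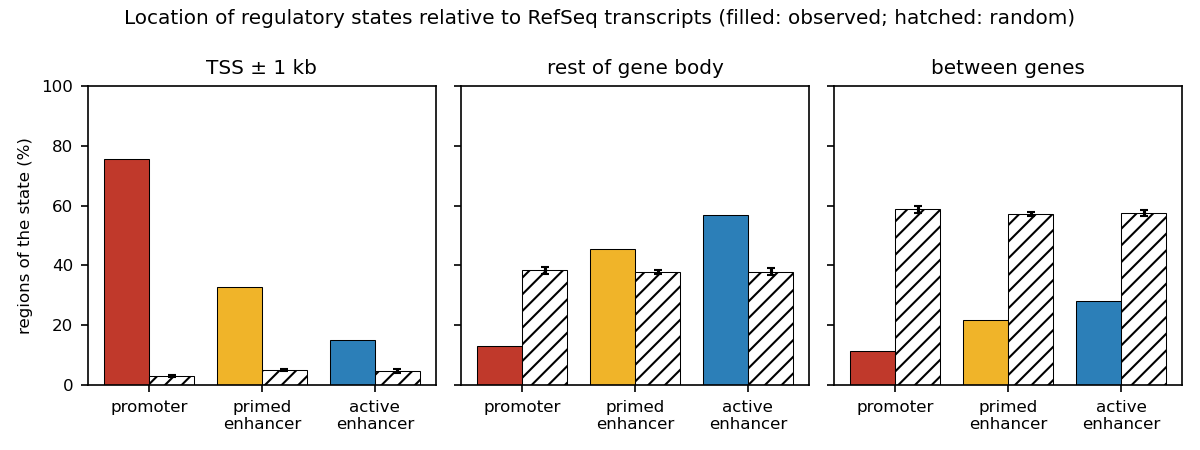
Percent of promoter, primed enhancer and active enhancer regions at a TSS, in the rest of gene bodies and between genes. Filled bars are observed values and hatched bars the mean of 100 random placements of the same lengths, with error bars from the lowest to the highest placement. Promoter regions reach 75.7% at the TSS and active enhancers 56.8% in gene bodies.

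Most promoter regions and active enhancers lay next to primed enhancers. Of the promoter regions, 83.9% directly touched a primed enhancer, 55.3% a non-regulatory region and 11.6% an active enhancer. Of the active enhancers, 84.9% touched a primed enhancer, 37.1% a non-regulatory region and 14.4% a promoter region. No random value was computed for touching. The median distance to the nearest promoter region was 16.4 kb for primed enhancers and 26 kb for active enhancers, against 150.6 and 150.2 kb for random placement. With regions under 1000 bp left out, these medians were 64.6 and 67.4 kb.

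The second measurement compared a heterochromatin mark with an active mark at each gene. It was the authors' ratio of H3K9me3 to H3K27ac over each RefSeq transcript on the autosomes and, for 18 transcripts, on unplaced contigs. A high value means more H3K9me3 relative to H3K27ac. It can come from much H3K9me3 or from little H3K27ac. The marks were not given separately per gene, so a high ratio alone does not show heterochromatin. The marks came from different sorts, and how the ratio was scaled to depth or input is not given in the sources used here, so a ratio of 1 is the nominal point of equality. Over 31161 transcripts the median was 0.902, with quartiles of 0.485 and 1.66, and 45.8% lay above 1. Over 22171 genes, each represented by its longest transcript, the median was 0.986. Transcripts listed at 0 numbered 1189, among them 879 of the 1083 transcripts under 200 bp. Genes with a value of exactly 0 are described only as listed at 0.

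Among genes of at least 5 kb outside the families listed by symbol pattern, the lowest ratios above 0 belonged to genes covered by promoter and active enhancer states. Cbln3 (NM_019820, chromosome 14, 55878920 to 55884256), a cerebellin of granule cells, had the lowest at 0.0526. Zbtb18, a transcriptional repressor of neuronal development (chromosome 1, 177444661 to 177450764), followed at 0.0567. The next were Tprn at 0.0593, Nrn1 (neuritin, a neurite growth factor) at 0.0655, Btbd17 at 0.0669, the homeobox gene Barhl2 at 0.0678, Trim62 at 0.0702, the chromatin remodelling subunit Smarcd2 at 0.0728, Cntnap1 (an axonal cell adhesion protein) at 0.0731 and Shf at 0.0756. All 10 overlapped an active enhancer, and all except Btbd17 had a promoter region at a TSS. The ratio and the states both drew on the H3K27ac library, so the overlap is not independent of the low ratios. A further 22 eligible genes were listed at 0, several of them with paired names such as Plac9a and Plac9b, Cphx1 and Cphx2, and Smok3a and Smok3b.

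Among the same genes, the 10 highest ratios ran from 7.03 to 14.1. Sprr2a1 and Sprr2a2, small proline-rich proteins of epithelia, shared 1 span (chromosome 3, 92215835 to 92222491) and a value of 14.1, and their signals cannot be told apart. Pou4f1 (NM_011143, chromosome 14, 104462325 to 104467999), a sensory neuron homeobox factor, had a ratio of 11.9, and the hypothalamic homeobox gene Otp (chromosome 13, 94875627 to 94883681) one of 8.42. The cytochrome P450 gene Cyp2a4 had 8.50, 2810047C21Rik1 8.00, the oocyte gene Oog1 7.83, the zinc finger gene Zfp955a 7.46, the ribosomal RNA precursor Rn45s 7.12 and AU018829 7.03. Members of gene families among them, and the repeated ribosomal RNA unit, are uncertain, since reads shared between copies were not analysed here. Zfp955a and Rn45s had a promoter region at a TSS, and the other 8 did not.

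Granule cell genes had the lowest median ratio of the 20 lists. All 20 members lay below 0.5, with a median of 0.162, below all 10000 random lists of the same size matched on gene length (95% of these between 0.622 and 1.58). A promoter region at a TSS was found at 18 of the 20, an active enhancer at 17 and a primed enhancer at 16. Here and in the lists below, states and ratios share the H3K27ac library and are not independent. The lowest were Zic2 at 0.0450 and Cbln3 at 0.0526, and the highest the potassium channel gene Kcnd2 at 0.434 and the vesicle priming gene Cadps2 at 0.459. Gabra6 had 0.0994 and Neurod1 0.133. Zic4 (0.115) and Fat2 (0.222), an atypical cadherin, lacked a promoter region at a TSS but overlapped active enhancers.

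General neuronal and synaptic genes followed in part. Of 18 measured, 14 lay below 1, with a median of 0.427 (percentile 0 among random lists). Promoter regions marked 14 and active enhancers 13. The kinase gene Camk2b, at 0.145, and the syntaxin gene Stx1b, at 0.170, were lowest. The 4 members above 1 were Nlgn1 at 1.30, Grin2b at 1.74, Camk2a at 1.74 and the AMPA receptor gene Gria1 at 2.41, and the last 3 had neither a promoter region nor an active enhancer. Grin2b and Camk2a encode a glutamate receptor subunit and a kinase of forebrain neurons. Syn1 and Syp are on the X chromosome and were not analysed here.

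Genes used by most cells also had low ratios. Housekeeping genes had a median of 0.426 (percentile 0.15), with 20 of 20 below 1, from Psmb4 at 0.0764 and Ubc at 0.103 to Snrpd3 at 0.785 and Tbp at 0.901. A promoter region marked 16 and an active enhancer 2, Ubc and Gapdh. Rpl13a and Rplp0 are also ribosomal protein genes. Chmp2a, Polr2a, Sdha and Tbp lacked a promoter region. Ribosomal protein genes had a median of 0.307 (percentile 0), with 68 of 68 below 1 and 1 of them listed at 0; 61 had a promoter region and 1 an active enhancer. Activity-dependent immediate early genes, transcribed within minutes of neuronal stimulation, had a median of 0.307 (percentile 0.17), with 12 of 13 below 1. Junb (0.0378) and Ier2 (0.0538) were lowest, and Bdnf (0.634) and Egr3 (1.47) highest. Here 10 had a promoter region and 5 an active enhancer. Among the 6 immediate early genes of at least 5 kb the median was 0.487 and its percentile 4.54, which no longer set the list apart.

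Markers of other cerebellar cell types had medians above 1, and 3 of these 6 lists were set apart from random lists. The H3K9me3 and H3K27ac libraries came from nuclei of different strains sorted in different ways. Inhibitory interneuron genes had a median of 2.00 (percentile 99.98), with 14 of 15 above 1 and none of the 15 with a promoter region or an active enhancer. The lowest were Prkcd at 0.972 and Lgi2 at 1.33, and the highest Ptf1a at 3.75 and Tfap2b at 3.7995, both transcription factors of GABAergic fate; the GABA synthesis genes Gad1 and Gad2 had 2.21 and 1.93. Purkinje cell genes had a median of 1.64 (percentile 97.31, just under the upper threshold), with 13 of 15 above 1. Gng13 (2.31) and Skor2 (2.21) were highest, and the 2 below 1 were Lhx1 (0.113), a LIM homeobox factor, and Dab1 (0.374), the adaptor of reelin signalling, both with a promoter region and an active enhancer. Promoter regions marked 4 of the 15 (percentile 12.18), also Slc1a6 (1.19) and Bcl11a (1.80).

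Endothelial and mural genes had a median of 1.85 (percentile 99.73), with 11 of 14 above 1. Kdr at 3.19 and Ly6c1 at 2.27 were highest. The 2 lowest, Emcn at 0.447 and Ptprb at 0.504, overlapped active enhancers, as did Pecam1 at 0.632 and Vwf at 1.58. None of the 14 had a promoter region at a TSS (percentile 0.015). H3K4me3, which marks promoters, came from fluorescence-sorted nuclei. H3K27ac and H3K4me1, which mark enhancers, came from size-gated nuclei of another strain, 92 to 96% of them granule cells. Active enhancers without promoter regions at these genes are therefore also a contrast of strain and sort, and their cell of origin was not tested. By the mean in place of the median the ratio's percentile was 96.35. Oligodendrocyte genes had a median of 1.71 (percentile 98.66), with 10 of 14 above 1. Olig1 at 4.798 and Opalin at 2.64 were highest and Cnp at 0.501 and Mbp at 0.651, both with a promoter region, lowest. Only Mbp overlapped an active enhancer. By the mean the percentile was 95.39, and among the 12 genes of at least 5 kb it was 92.36.

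Astrocyte and Bergmann glia genes did not stand apart by the ratio, with a median of 1.20 (percentile 77.65) and 6 of 15 below 1. Gdf10 at 2.59 and Aqp4, the water channel of astrocyte endfeet, at 2.20 were highest, and Timp4 at 0.144 and Agt at 0.430 lowest. Timp4 lies inside the neuronal gene Syn2 (0.248), so its signal cannot be separated from that gene. Promoter regions marked 3 of the 15, Timp4, Slc1a2 and Hopx. Microglia genes had a median of 1.27 (percentile 80.39) with 8 of 11 above 1, from P2ry12 at 0.734 and Siglech at 0.827 to Ctss at 1.78 and Fcrls at 2.04. None of the 11 had a promoter region at a TSS (percentile 0.22). P2ry12 and Spi1 overlapped an active enhancer, and P2ry12 lies inside Med12l (0.678). The contrast of strain and sort given for endothelial genes also applies to these active enhancers without promoter regions.

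Genes of granule cell progenitors and early differentiation, below called progenitor genes, were divided. Their median of 1.20 lay within the random range (percentile 78.54), with 8 of 19 below 1. Nhlh2 (0.118), a neuronal basic helix-loop-helix factor, and Hey1 (0.143) were lowest, and Cntn2, an axonal adhesion protein, and Ptch1, the sonic hedgehog receptor, had 0.192 and 0.229; these 4 had a promoter region and an active enhancer. Barhl1 (0.419) was the remaining member with a promoter region. The highest were Sox2 at 2.27, which lies inside Sox2ot (2.28), and Sfrp1 at 1.91. Atoh1, which specifies granule cell precursors, had 1.699 and was wholly inside a primed enhancer, and the proliferation genes Mki67, Top2a and Cdk1 had 1.62, 1.20 and 1.35, while Pcna had 0.745 and the cyclin gene Ccnd1 0.299, all 5 with no promoter region. Primed enhancers overlapped 15 of the 19 (percentile 99.29, and 96.495 when enhancers within 10 kb were counted).

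Genes of DNA methylation and hydroxymethylation, the subject of the series, ranged from 0.233 to 1.37 with a median of 0.675 (percentile 5.89; 0.4 by the mean). The de novo methyltransferase gene Dnmt3a (0.233; chromosome 12, 3806980 to 3914443) and the 5-methylcytosine oxidase gene Tet3 (0.274; chromosome 6, 83362374 to 83441678) were lowest, each with a promoter region and with 10000 and 7600 bp of active enhancer. Tet1 had 0.509 and Tet2 1.37, the highest of the list, followed by Dnmt3b at 1.23. A promoter region marked 10 of the 15 and an active enhancer 3, Dnmt3a, Tet3 and Tet1. Tdg (0.642) shares 98.9% of its span with Gm9855.

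Genes of other lineages and several large gene families had high ratios. Transcription factors of non-neural lineages had a median of 1.88 (percentile 99.85) with 18 of 19 above 1 and no promoter region. Pdx1 (4.33) and Cebpa (3.65) were highest and Myog (0.235) and Hnf1a (1.03) lowest. Myog, the muscle factor, lay wholly inside a primed enhancer, as did Myod1 at 1.48. Only Hnf1a overlapped an active enhancer. All 39 Hox genes lay above 1, with a median of 3.35 (percentile 100), none with a promoter region or an active enhancer and 16 with a primed enhancer. Olfactory receptor genes had a median of 2.499 with 1026 of 1096 above 1, and vomeronasal receptor genes 2.59 with 268 of 324 above 1 (percentile 100 for both). Their median lengths were 0.945 and 0.96 kb, but the vomeronasal list also holds longer genes, such as Vmn2r46 at 15936 bp. Random lists had medians of 0.262 for olfactory and 1.04 for vomeronasal receptor genes. These are unlike baselines, since random lists drew only on genes outside the list. Olfactory receptor genes could therefore enter the vomeronasal random lists but not the olfactory ones. In the shortest length quartile 739 of 5543 genes were listed at 0, and how far such genes lower the random medians was not tested. Listed at 0 were 9 olfactory and 43 vomeronasal receptor genes. Of the 1096 olfactory receptor genes none had a promoter region or an active enhancer. Keratin genes had a median of 1.87 (percentile 100) with 42 of 47 above 1. The random lists were not matched on position, so neighbouring Hox, receptor and keratin genes were counted as if independent.

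Taken as whole lists, Zfp zinc finger genes and clustered protocadherins combined opposite features. Zfp genes had a median ratio of 0.993, inside the random range (percentile 79.68), yet 193 of 323, or 59.8%, had a promoter region at a TSS against 39.6% in random lists (percentile 100). By the mean the ratio's percentile was 100, and among the 300 of at least 5 kb it was 99.06. The list holds symbols of Zfp followed by digits only, so genes such as Zfp955a are not in it. Clustered protocadherins, the adhesion molecules that give neurons distinct surface identities, had a median of 1.99 (percentile 100) with 41 of 58 above 1. Only 4 had a promoter region, and 36 overlapped an active enhancer, or 62.1% against 20.7% in random lists (percentile 100). High ratios and active enhancers lay partly in different members. The 22 beta genes had a median of 3.75 and no active enhancer. All 22 gamma genes overlapped one, with a median of 0.608. The 14 alpha genes also all overlapped one, with a median of 2.0998. Among the 38 protocadherins of at least 5 kb the median was 1.06 and lay inside the random range (percentile 36.76). Transcripts of the alpha and gamma clusters overlap each other, so neighbouring members share signal.

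**Figure D3:**
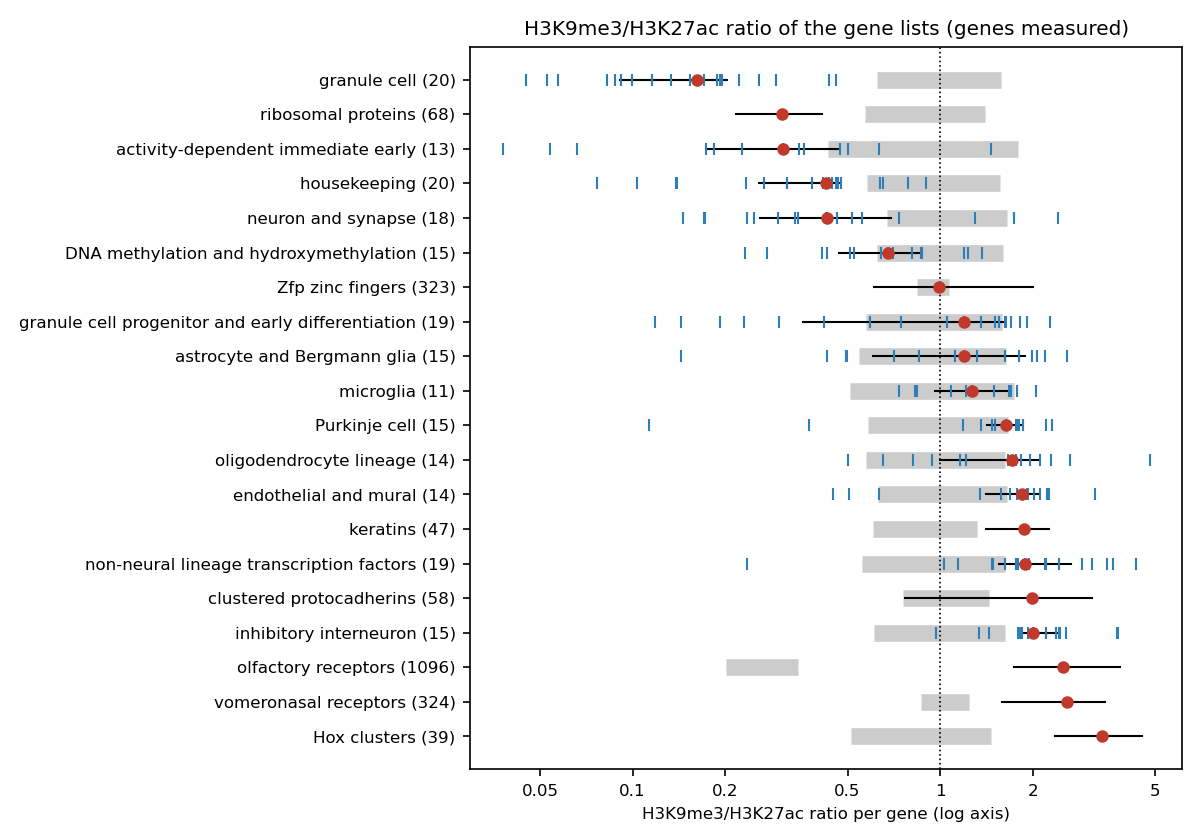
H3K9me3/H3K27ac ratio (log axis) of the 20 gene lists, with the number of genes measured in brackets. Red points are list medians, black lines the quartiles, blue ticks the members of lists fixed by symbol, grey bars the central 95% of medians of 10000 length-matched random lists, and the dotted line a ratio of 1; 3 pattern lists hold genes listed at 0, which enter the medians. Granule cell genes have the lowest median (0.162) and Hox genes the highest (3.35).

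Genes with a promoter region or an active enhancer had lower ratios than genes with neither. The median was 0.591 for 8137 genes with a promoter region at a TSS, 0.467 for 999 genes with an active enhancer and no promoter region, 1.06 for 3334 genes with primed enhancers only and 1.69 for 9701 genes with none of these. Among promoter-marked genes, the 1608 that also overlapped an active enhancer had a median of 0.360 and the 6529 others 0.646. The order of genes with a promoter region and genes with no state was the same in each length quartile, from 0.240 against 1.68 among the shortest genes to 0.698 against 1.78 among the longest. Genes with primed enhancers only had medians of 0.466, 0.827, 1.02 and 1.53 from the shortest to the longest quartile. The segmentation and the ratio both used the H3K27ac library and the inputs, so this relation is not between independent measurements.

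**Figure D4:**
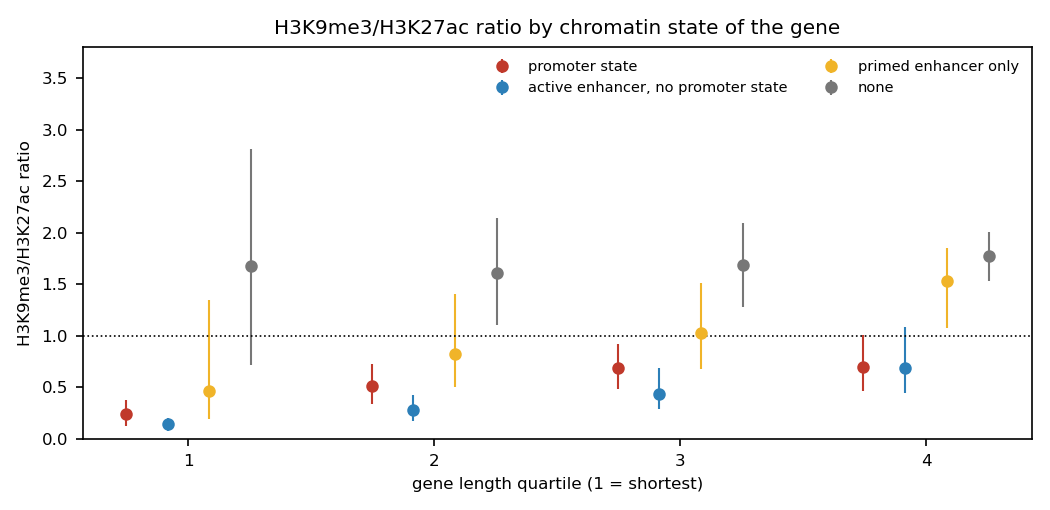
H3K9me3/H3K27ac ratio of genes by chromatin state and gene length quartile. Points are medians and lines reach the quartiles; the dotted line is a ratio of 1. Genes with none of the regulatory states lie between 1.61 and 1.78 in every length quartile, and genes with a promoter region between 0.240 and 0.698.

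Chromosome medians of the ratio ran from 0.747 on chromosome 11, with 1731 genes, to 1.26 on chromosome 6, with 1229 genes. Among genes of at least 5 kb, the highest median was on chromosome 13, at 1.303 over 667 genes. The X chromosome, which differs in number between the pooled males and females, has no ratio analysed here.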

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

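The tests on gaps were chosen before their results were seen, but a minimum number of expected gaps was added after the value for the Y chromosome had been seen, and the reading of the share of X genes was set back to its prediction after that share had been seen. On the X and Y chromosomes only non-regulatory regions were listed, and they leave gaps between them, 360 on X and 101 on Y. They stood out as a signal in sequence that none of the comparisons used, since on the autosomes the 4 states leave 0 bp uncovered. The gaps had a median length of 2200 bp on X and 1200 bp on Y, against 3000 bp for the 24027 stretches of promoter or enhancer state on the autosomes.

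On X, 41.7% of the gaps came within 1 kb of an end of a protein-coding gene, against 4.92% for random placement (1.67 to 7.78% over 100 placements) and 38.6% for the autosomal stretches. This is consistent with regulatory regions that were called on X and left out of the lists. Mecp2 (chromosome X, 74026592 to 74085690) held a gap of 4000 bp from 74079001 to 74083000. That gap lay inside the gene, more than 1 kb from either end. Syn1 had one of 3800 bp, Syp one of 1000 bp and Pgk1 one of 4600 bp, each within 1 kb of an end. Plp1, Dcx, Hprt and Gata1 had none in the gene or within 1 kb of it. The state of a gap is unknown. On Y, 6.93% of the gaps (7 of 101) lay at a gene end against 1.79% at random (0 to 5.94%). That is 3.87 times random and met the prediction as first written, but so few gaps were expected at random that the Y gaps were left undecided.

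Gaps were fewer at X genes than promoter or enhancer stretches at autosomal genes. Of the protein-coding X genes, 16.1% had a gap at an end, against 43.4% on the lowest autosome (chromosome 7) and 60.3% on the highest (chromosome 11). Fewer X copies in the pooled males and females predict a lower share, as was found, so they may contribute. The same share is open to the different gene content of X and to the inactive X of females, which were not tested.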

How the results depend on the processing

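With 1 library per mark no spread between replicates could be set against any change, the depth is unknown, and the cause of each change was not tested except where the setting itself changes what is counted. Leaving out misplaced rows, keeping them and leaving out values at 0 were chosen after the data were seen. Of the 60 list ratios recomputed with the mean, with genes of at least 5 kb or with unmatched random lists, 52 kept their side of the thresholds, as did 120 of 140 state shares. Keeping misplaced rows left the 20 list medians as they were, and leaving out values at 0 left 17, so these settings say little of stability.

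Among list ratios, the mean gave percentiles of 95.39 for oligodendrocyte, 96.35 for endothelial, 0.4 for DNA methylation and 100 for Zfp genes. Genes of at least 5 kb gave 92.36 for oligodendrocyte, 4.54 for immediate early, 36.76 for protocadherin and 99.06 for Zfp genes, where the protocadherin list fell to the other side of the middle when its 20 genes shorter than 5 kb, which have high ratios, were left out. Taking only members with a promoter region, possible for the 8 lists with at least 5 of them, moved progenitor genes to 0.1 and Zfp genes to 1.89. A low percentile is fixed by that choice, since the random lists came from all genes and promoter-marked genes have lower ratios, so it bears on neither list. Against promoter-marked genes the Zfp genes lay at percentile 100.

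For primed enhancers, random lists not matched on length gave percentiles of 99.715 for granule cell (97.225 in the main setting), 99.965 for neuron (96.835), 98.855 for Purkinje (96.55), 10.545 for interneuron (2.26) and 14.78 for endothelial genes (2.49), so the last pair lost their call and the others gained one. Unmatched lists gave 98.86 for promoter states at DNA methylation genes (95.28) and, for active enhancers, 0.35 for Hox (7.195), 0.395 for Zfp (4.79), 1.16 for keratin (9.735) and 0.105 for ribosomal protein genes (14.44), all gained. Counting enhancers within 10 kb gave, for primed enhancers, 99.655 for granule cell, 98.775 for Purkinje, 23.84 for interneuron, 96.495 for progenitor (99.29), 92.755 for DNA methylation (98.605) and 99.09 for Hox genes (51.835), and, for active enhancers, 0.31 for Hox, 0.005 for Zfp and 0.28 for keratin genes. Of these, interneuron, progenitor and DNA methylation genes lost their call. With a TSS window of 5000 bp the promoter share of oligodendrocyte genes was at 1.675 (2.59).

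Regions of at least 1000 bp numbered 4370 for promoters. They covered 0.250% of the genome for promoters, 3.68% for primed and 0.907% for active enhancers, with X and Y counted in the genome but not in these lists. On autosomes alone the states covered 0.381% (promoter), 94.4% (non-regulatory), 4.16% (primed) and 1.05% (active). The shares at a TSS for promoters, primed and active enhancers were 73.1, 21.2 and 11.4% with a window of 500 bp and 80.8, 43.6 and 25.5% with 5000 bp. They were 72.2, 12.7 and 8.36% when at least 50% of the region had to overlap, and 90.3, 33.7 and 14.0% for regions of at least 1000 bp. Median distances to a promoter were 19.1 (primed) and 28.2 kb (active) between midpoints, and 64.6 and 67.4 kb for regions of at least 1000 bp.

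The share of transcripts above 1 was 48.7% with 1 row per symbol, 50.0% above the median of all and 47.7% without values at 0. Median ratios by state at 5 kb or longer were 0.640 (promoter), 0.514 (active) and 1.17 (primed). With enhancers within 10 kb they were 0.549 (active), 1.16 (primed) and 1.79 (none). Primed genes had 1.13 with a window of 5000 bp, and genes with none had 1.67 with misplaced rows kept and 1.74 without values at 0. The lowest chromosome median was 0.704 without the pattern lists.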

Other observations

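The tests in this part were all chosen after the data were seen. Besides the families described next, 6 further groupings were looked at: transcript type, gene length, chromosome, genes with the most active enhancer, promoter regions without a TSS, and repeated values of short transcripts. The chromosome medians given above had been planned. Zfp zinc finger genes with a promoter region had higher ratios than other promoter-marked genes. The median of the 193 was 0.809, against 0.587 for random lists of promoter-marked genes matched on length (95% between 0.532 and 0.638, percentile 100), and 19.2% lay above 2 against 1.04%. Of the 133 promoter-marked genes above 2, 37 were in the Zfp list, or 27.8%, against 2.37% of all promoter-marked genes. Of the 81 Zfp genes above 2, with or without a promoter region, 20 lay on chromosome 13 and 16 on chromosome 17. The random lists were not matched on position, so neighbouring Zfp genes were counted as if independent. Reads shared between family members were not analysed here. The list holds symbols of Zfp followed by digits only, so further zinc finger genes such as Zfp955a (7.46) and Zfp955b (4.38) are not counted. Examples were Zfp935 at 6.99 (chromosome 13, 62453016 to 62466812), Zfp369 at 5.54, Zfp942 at 5.39 and Zfp2 at 4.89. The 130 Zfp genes without a promoter region had a median of 1.403, within the random range (percentile 32.6), although 33.8% lay above 2 against 22.3% (percentile 99.86).

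Within the clustered protocadherins the subclusters differed. The 22 beta genes, with a median length of 3.33 kb, all lay above 1 with a median of 3.75, and none had a promoter region or an active enhancer. The 14 alpha genes had a median of 2.0998, with 13 above 1, and the 22 gamma genes a median of 0.608, with 6 above 1. All alpha and gamma genes overlapped an active enhancer. Alpha and gamma transcripts run through much of their cluster, with median lengths of 204.5 and 113.4 kb, so their values overlap.

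The genes with the most active enhancer sequence were ranked by total length, which favours long genes. Ntm, a neuronal adhesion gene, had 186.6 kb, Msra 103.4 kb, the Rac regulator gene Chn2 101.2 kb, Tspan9 95.4 kb and the splicing regulator gene Celf4 95.2 kb, with ratios of 0.368, 0.209, 0.170, 0.182 and 0.187. Active enhancers covered 64.7% of the actin regulator gene Coro2b and 68.2% of Fam53b. Promoter regions without a TSS within 1 kb numbered 2301, or 24.3%, and 1576 of them had none within 10 kb. Among transcript types, 592 microRNA genes had a median of 0 with 432 listed at 0, and 1643 long non-coding RNA genes a median of 1.32. Some values recurred among short transcripts, such as 1.159 in 24 and 0.773 in 19 of them. These were 6 and 4 times 0.193, a value found in 8, so such ratios moved in coarse steps.

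Of 8739 coding (NM) rows with another coding row of the same span, 97.2% matched, so some of these differed too. Among non-coding rows, transcripts with the same span but different ratios were concentrated at the end of the accession order. The point where that stretch begins was set from the same matches. The lack of own values after it was therefore partly fixed by this choice. Before that point 97.7% of 691 non-coding (NR) rows matched another transcript of the same span, which argues against signal measured over exons and not over the span. In the last 190 rows, 88.5% of the 52 rows that could decide (46) held the value of the next row and 0 held their own, consistent with values moved by 1 row. For example, Trub2 (NR_110962) was listed at 0.105, the value of Dolpp1, where the coding transcripts of Trub2 have 0.834. No biological explanation was tested, and the 447 rows before this stretch stay undecided.

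Genes of at least 5 kb listed at a ratio of 0 numbered 61. Several share a span, such as Fam177a and 1700047I17Rik2, and each was counted, so the 61 are not separate loci. Of these, 78.7% had a non-overlapping gene of the same length within 1% and 5 Mb, against 47.5% in length-matched lists (34.4 to 59.0%), consistent with reads not placed in near-identical copies. This test replaced one on the share with any promoter or enhancer state, which was 23.0% against 57.4%, and pairs such as Smok3a and Smok3b had been seen before it was chosen. A promoter region marked 13.1% of the 61 against 37.7%. Where reads are not placed no promoter could be called either, so whether active genes without H3K9me3 are among them stays open. Mappability was not analysed here, so the extent of such copies stays open.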
